A study of Mus musculus with 6 samples.

How the data were processed

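MicroRNA (miRNA) levels were measured on 6 one-colour Agilent mouse miRNA microarrays, each hybridised with Cy3-labelled total RNA from cartilage microdissected from the femoral growth plate of 12-day-old C57BL/6 mice. The arrays fell into 3 zones of 2 arrays each (proliferative, prehypertrophic and hypertrophic), assigned from the zone stated for each sample. Per the labels, each array received 100 ng of RNA from a pool of 5 growth plates, on a slide designed from miRBase version 14, and the authors analysed the scans in GeneSpring. The labels do not say which animals went into which pool, or whether the zones of different arrays came from the same animals. P-values thus measure the spread between these 6 samples, except where a floor on dim signals set that spread, as described below.

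Spot brightness was used as the deposited intensity on a linear scale: per the file headers, the authors' scans were processed with Feature Extraction 10.7.3.1, which subtracts a background and gives a processed signal per spot, flags for outliers and for spots well above background, and a total signal per miRNA. The authors also deposited a log2 value table of the same arrays. Set against the scanner files, each column of that table equalled log2 of the total signal per miRNA, with signals under 1 set to 1, minus a constant for that array close to its 75th percentile, with departures of at most 1.4e-06, so its scale, centring and direction were settled. Its column medians lay at -4.399 and -4.254 for the proliferative, -4.46 and -4.455 for the prehypertrophic and -4.689 and -4.943 for the hypertrophic arrays. It served as an alternative.

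Each array held 13800 miRNA spots, from 1928 probes for 690 mouse miRNAs. Spots flagged as outliers (384 to 515 per array) and control spots were left out, and no spot was saturated. Processed signals of the spots of one probe were averaged. A probe counted as well above background where most of its unflagged spots carried that flag. Only 342 probes (17.7%) did so on all 6 arrays, so each array was scaled to its 75th percentile over these probes. A floor of 12.66 scaled units (3.66 on the log2 scale), the median over arrays of the lowest scaled signal well above background, was then applied before log2 was taken. Each miRNA was represented by its brightest probe. Tests covered 226 miRNAs whose probe was well above background on both arrays of at least 1 zone. Where a miRNA was well above background on no array of a zone, only a bound is given ("at least N-fold"): the mean of the brighter zone against, per array of the dimmer zone, the highest of the floor, the lowest signal well above background and the probe's own signal. Where both arrays of a zone lay at the floor, as for miR-126-3p and miR-181a in the proliferative zone, the floor set their spread to 0. The p-value of such a miRNA therefore leaves that spread unmeasured. No level of one miRNA was set against that of another. The number of arrays limits the precision.

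Contrasts between zones were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) on all 6 arrays with zone as the factor, which leaves 3 residual degrees of freedom before the spread is shared across miRNAs (prior degrees of freedom 7.83). P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. A contrast of the mean of the proliferative and hypertrophic zones minus the prehypertrophic zone (curvature) and an F test over the 3 zones used the same fit. Of 23 miRNA lists, 9 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over 27 tests, and again with an estimated correlation and with fry. Every adjusted p of a miRNA in the text comes from limma and every adjusted p of a list from camera unless fry is named. Zones, contrasts, lists, alternatives and the rule for naming miRNAs were set before the data were examined. The rule took, per contrast, up to 10 rises and 10 falls past the threshold without overlap between arrays, the smallest p-values where fewer than 10 passed, up to 4 members of each list, miR-140, miR-140*, miR-455, miR-455*, miR-322 and miR-210 always, and for curvature up to 5 miRNAs past the threshold. Any other miRNA named was chosen after its values were seen.

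All arrays shared one slide and scan date. Both hypertrophic arrays lay in row 1 of the slide and both prehypertrophic arrays in row 2, with 1 proliferative array in each. A difference between the prehypertrophic and hypertrophic zones thus cannot be told apart from one between rows, except through the proliferative pair. The numbers in the sample titles form 2 runs of 3, each with 1 array per zone. The first proliferative, first prehypertrophic and second hypertrophic arrays have title numbers 13 to 15, and the other arrays 16 to 18. No label says that a run is a batch, and the arrays were not paired in the fit. Differences between the runs correlated across miRNAs at 0.59 between the proliferative and prehypertrophic zones and at 0.73 between the proliferative and hypertrophic zones. Between the prehypertrophic and hypertrophic zones the correlation was 0.29. These values include miR-671-3p and miR-342-3p, whose run differences were large in every zone (5.07, 4.37 and 3.71, and 2.01, 2.11 and 2.30 log2 units, in zone order). No correlation was taken without them, so how far the other miRNAs of a run deviated together stays open. The pairing thus comes from the title numbers and these correlations, and the run was fitted as a block as an alternative. Other alternatives changed the signal column, the probe rule, the scaling, the filter, the floor, the variance model, the slide row and the arrays used, and left out each array in turn. The background alternative (normexp, offset 50) used the median spot signal, because the scanner files hold no mean signal. Gene neighbours and names were taken from RefSeq (GRCm38.p6), without coordinates because the file headers name another build. Of 690 array names, 567 matched 1 RefSeq miRNA gene, 78 matched several and 45 matched none.

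The procedure was tested on simulated arrays for the hypertrophic minus proliferative comparison, with the 226 miRNAs' own means. Their spreads were those of limma after sharing across miRNAs, and no floor was applied. The recovery below thus assumes limma's own model of the spread. In 20 simulations with 40 changed miRNAs each, 100% of changes of 2 log2 units and 69% of changes of 1 log2 unit were recovered, with a mean of 1.55 false calls. The simulated arrays varied independently, so these shares leave out any deviations that arrays of one run had in common. A shift of 0.7 log2 units was planted in the let-7 list. Camera called it in 20 of 20 simulations at the preset correlation and in 0 of 20 with an estimated correlation. The simulated miRNAs varied independently of one another, whereas the correlation estimated in the data was 0.63 for this list. The simulations thus do not show that the preset correlation suits lists whose members vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.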

Results

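The growth plate lengthens long bones as its chondrocytes pass from a proliferative zone through a prehypertrophic zone into a hypertrophic zone, which borders vessels and forming bone. Levels of 690 mouse miRNAs were compared among these 3 zones, microdissected from the femoral growth plate of 12-day-old C57BL/6 mice, with 2 arrays per zone and a pool of 5 growth plates on each array. The comparison asked how miRNA levels differed as chondrocytes mature. Between 24.2% and 27.9% of miRNA spots per array were well above background. On both arrays of a zone, 201 miRNAs were well above background in the proliferative, 207 in the prehypertrophic and 216 in the hypertrophic zone, and 186 were so on all 6 arrays. Across the tested miRNAs, log2 signals of arrays of one zone correlated at 0.955 to 0.977, and those of arrays of different zones at 0.902 to 0.968. miRNAs are not independent replicates, so these values only describe the arrays.

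Most calls came from the comparison of the outer zones. In the hypertrophic zone miR-451, an erythroid miRNA, was 18.1-fold higher than in the proliferative zone (log2 fold change 4.18, SE 0.25, adjusted p = 9.57e-07), at 7.91 ± 0.12 (log2 scaled signal, SD, n = 2) against 3.72 ± 0.09 (SD, n = 2). It was well above background on 1 of the 2 proliferative arrays, the other lying at the floor, so the size is loose: over the other settings the log2 fold change was 1.90 to 6.09, and by its other probe 3.25. miR-322, the mouse counterpart of human miR-424, was 4.94-fold higher (SE of log2 0.28, adjusted p = 4.40e-04). miR-127, an imprinted miRNA, fell by 1.78 on the log2 scale (SE 0.28, adjusted p = 0.00169), from 8.65 ± 0.42 (SD, n = 2) to 6.87 ± 0.11 (SD, n = 2). In all, 33 of 226 miRNAs passed the limma threshold, 13 higher and 20 lower in the hypertrophic zone, and for each of the 33 both arrays of one zone lay above both of the other, which chance gives for 33.3% of unchanged miRNAs. Within the runs of title numbers, the log2 fold change of miR-451 was 4.20 and 4.16, that of miR-322 2.16 and 2.45 and that of miR-127 -2 and -1.55.

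The count of rises and falls past the threshold depended on the scaling. It was 10 higher and 1 lower with the 75th percentile of all probes, 11 and 1 with median scaling, 11 and 8 with quantile normalization and 15 and 0 without scaling. Relative to the values used here, the median of all miRNAs shifted by 0.48 log2 units without scaling and by 0.11 with median scaling. With the 75th percentile of all probes and with quantile normalization it shifted by 0.01 each. With the 75th percentile of all probes the list medians of let-7 and of miR-199 with miR-214 stayed at -0.86 and -0.73, so these falls kept their size under that scaling. They were smaller under the others: -0.65 and -0.66 with quantile normalization, -0.75 and -0.62 with median scaling and -0.38 and -0.25 without scaling. The 75th percentile of all probes moved the 2 hypertrophic arrays in opposite directions, by -0.211 and 0.137 log2 units. Single arrays mattered too: 13 miRNAs passed without the first proliferative array (10 higher and 3 lower), 45 without the second (12 higher and 33 lower), 2 without the first hypertrophic array and 1 without the second, these last all higher.

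**Figure D1:**
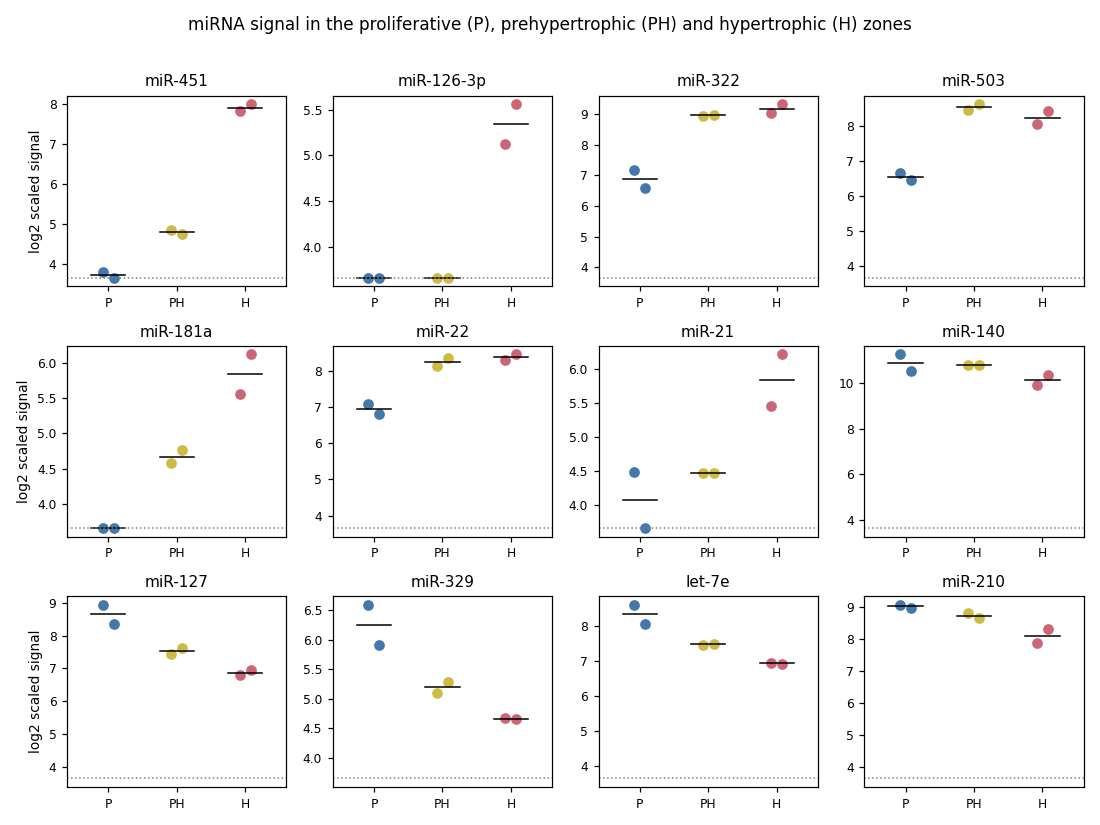
Log2 scaled signal (vertical axis, separate range per panel) of 12 miRNAs in the proliferative (P), prehypertrophic (PH) and hypertrophic (H) zones. Each point is 1 array, black lines are means of 2 arrays and the dotted line is the floor at 3.66; miR-451 averaged 3.72, 4.79 and 7.91 in P, PH and H.

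Further rises in the hypertrophic zone included miR-126-3p, an endothelial miRNA, which was at least 2.75-fold higher (adjusted p = 0.00169) and well above background on no proliferative array, a call that held in 17 of 21 other settings, with fitted log2 fold changes of 0.48 to 5.19. Another probe of miR-126-3p, also well above background on no proliferative array, differed by 1.04 log2 units. miR-21 was 3.37-fold higher (SE of log2 0.34, adjusted p = 0.00628) and lay at the floor on 1 proliferative array. Its call held in 9 of 21 other settings. miR-22 was 2.71-fold higher (SE of log2 0.26, adjusted p = 0.00381). miR-2132, a name with no mouse miRNA gene in RefSeq, was 3.59-fold higher (SE of log2 0.27, adjusted p = 0.00139). A list call below rests on camera's preset correlation. All 12 calls among 27 tests were lost with an estimated correlation, where the smallest adjusted p was 0.533. Fry gave 0 calls for a shift in one direction (smallest adjusted p = 0.0934) and 7 for changes in either direction. These 7 belonged to the cartilage list, the list of miR-322 and miR-503 and the miR-181 list. Between the outer zones the let-7 and Dlk1-Dio3 lists each had a fry adjusted p of 0.0503 for changes in either direction.

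Of 4 tested miR-181 miRNAs, a family of closely related sequences, 3 rose and 1 did not pass (3 also adjusted over the list alone; camera adjusted p = 8.22e-04, and adjusted p = 0.533 with an estimated correlation). miR-181a was at least 3.89-fold and miR-181a-1* at least 3.92-fold higher in the hypertrophic zone (adjusted p = 4.40e-04 for each), neither being well above background on a proliferative array. Another probe of miR-181a, also not well above background there, differed by 0.74 log2 units. miR-181b was 3.53-fold higher (adjusted p = 0.00204), while miR-181d differed by 0.18 log2 units (adjusted p = 0.797). In the X-linked cluster of miR-322 and miR-503, 2 of 7 tested members rose and none fell (2 adjusted over the list alone; camera adjusted p = 0.0135, and adjusted p = 0.675 with an estimated correlation). These were miR-322 and miR-503, the latter 3.24-fold higher (SE of log2 0.26, adjusted p = 0.00169). The other arm of the miR-322 hairpin, miR-322*, did not pass (0.67 log2 units, adjusted p = 0.183). Their neighbour miR-542-5p (0.30 log2 units, adjusted p = 0.651) did not pass either. miR-322 may have been chosen by the study on these samples, so this list is not independent evidence of its direction. The list call was lost with the slide row as a block (adjusted p = 0.116), without scaling (0.184), without a filter on dim miRNAs (0.0614), without the second hypertrophic array (0.167) and without the second proliferative array (0.147).

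Among 18 tested miRNAs of the imprinted Dlk1-Dio3 cluster, 8 fell and 10 did not pass (8 adjusted over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.533 with an estimated correlation). Beside miR-127, miR-329 fell by 1.59 (SE 0.29, adjusted p = 0.0039), miR-434-3p fell by 1.39 (SE 0.30, adjusted p = 0.0118) and miR-379 fell by 1.38 on the log2 scale (SE 0.40, adjusted p = 0.0393). The log2 fold change of miR-379 was -2.04 and -0.73 within the runs of title numbers, -0.66 without the first and -2.10 without the second proliferative array. miR-299*, miR-154 and miR-337-5p fell too, with log2 fold changes of -1.35 and -1.17 for the first and last and miR-154 at least 2.49-fold lower. Over the other settings the calls of miR-379 and miR-299* held in 11 of 22 each, that of miR-154 in 11 of 21 and that of miR-337-5p in 10 of 21. The eighth was miR-382 (-1.10, adjusted p = 0.0378), named after its value was seen. Without the first proliferative array 2 of the 8 passed, and without either hypertrophic array 0. The list call was lost without a filter on dim miRNAs (adjusted p = 0.0983) and with 2 times the floor (0.0576). In the let-7 and miR-98 list, 4 of 10 tested members fell (7 adjusted over the list alone; camera adjusted p = 0.00109, and adjusted p = 0.675 with an estimated correlation). let-7e fell by 1.39 on the log2 scale (SE 0.27, adjusted p = 0.00628), let-7b by 1.07 and let-7c by 0.90, while miR-98 had a log2 fold change of -0.88 (adjusted p = 0.0591). The call of let-7c held in 8 of 22 other settings. The mature let-7 sequences are nearly identical, so signal from one can reach the probes of another.

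None of the 4 tested miRNAs of the list of miR-199 and miR-214, transcribed in mesenchymal cells, passed over all miRNAs, and 3 were lower adjusted over the list alone (camera adjusted p = 0.0342, and adjusted p = 0.675 with an estimated correlation). This list call held in 12 of 24 other settings and was lost without the first proliferative (adjusted p = 0.123), the first hypertrophic (0.115) or either prehypertrophic array (0.0548 each). Their log2 fold changes were -0.92 for miR-199b*, -0.75 for miR-214, -0.72 for miR-199a-5p and -0.62 for miR-199a-3p. In the cartilage list 1 of 7 tested members rose, 1 fell and 5 did not pass. Adjusted over the list alone, 1 was higher and 4 were lower. The camera adjusted p was 0.331, and the fry adjusted p for changes in either direction was 0.00343. miR-193b was 2.23-fold higher (adjusted p = 0.0177), a call that held in 12 of 22 other settings, and miR-675-3p, processed from the imprinted H19 transcript, was at least 1.82-fold lower (adjusted p = 0.0393), a call that held in 7 of 21 other settings. The chondrocyte miRNA miR-140 had a log2 fold change of -0.76 (SE 0.30, adjusted p = 0.13), miR-140* of -0.98 (SE 0.31, adjusted p = 0.0534), miR-455 of -0.78 (SE 0.25, adjusted p = 0.0579) and miR-455* of 0.37 (SE 0.27, adjusted p = 0.488), so that none of these passed. miR-210, induced by hypoxia, fell by 0.94 on the log2 scale (SE 0.26, adjusted p = 0.0393), from 9.03 ± 0.07 to 8.09 ± 0.30 (SD, n = 2 each), but this call held in 6 of 22 other settings, with log2 fold changes of -1.15 to -0.46.

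**Figure D2:**
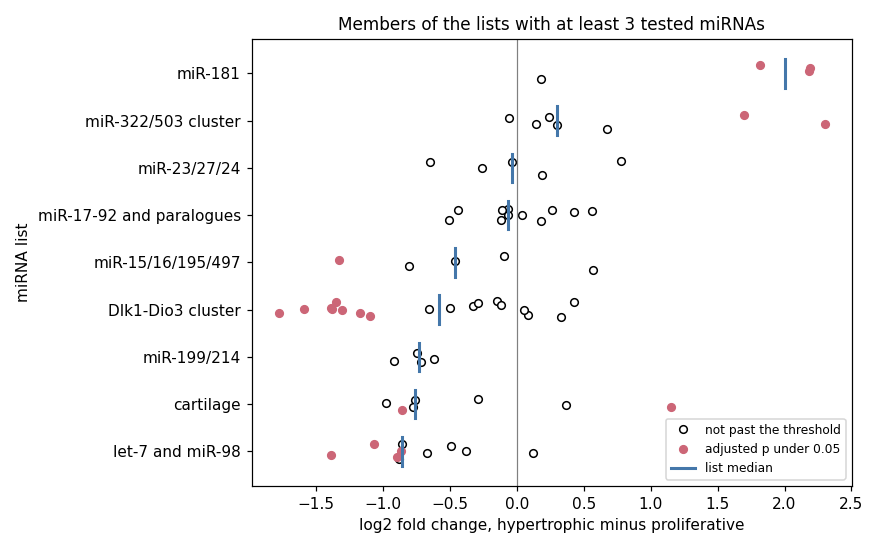
Log2 fold change, hypertrophic minus proliferative (horizontal axis), of each tested member of the 9 lists with at least 3 tested members (vertical axis); filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. The miR-181 median lies at 2, and those of the let-7, cartilage and Dlk1-Dio3 lists and of the list of miR-199 and miR-214 between -0.86 and -0.58; for let-7, cartilage, Dlk1-Dio3 and miR-199 with miR-214 they were -0.86, -0.76, -0.53 and -0.73 with the 75th percentile of all probes, -0.65, -0.63, -0.56 and -0.66 with quantile normalization, -0.75, -0.65, -0.49 and -0.62 with median scaling and -0.38, -0.28, -0.18 and -0.25 without scaling.

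In 3 other lists camera gave no call. For the family of miR-15, miR-16, miR-195 and miR-497, 1 of 5 tested members fell, miR-15b by 1.33 on the log2 scale (adjusted p = 0.0275), a call that held in 11 of 22 other settings, while miR-497 (-0.81, adjusted p = 0.122), miR-195 (-0.46) and miR-15a (0.57) did not pass (list adjusted p = 0.331). The list median was -0.46, and 0.03 without scaling. None of 11 tested miRNAs of the cluster of miR-17 to miR-92a and its paralogues, linked to proliferation, passed the limma threshold, with log2 fold changes of 0.56 for miR-19a, -0.51 for miR-93, -0.44 for miR-25 and 0.43 for miR-20b (list adjusted p = 0.802). Its median was -0.07 (-0.06 to 0.41 with the other scalings) and its mean 0.01, and camera's direction was up. None of 5 passed in the miR-23/27/24 list, which held miR-27a (0.78), miR-23b (-0.65), miR-27b (-0.26) and miR-23a (0.19) (list adjusted p = 0.915, median -0.04 with camera's direction up, and -0.10 to 0.44 with the other scalings).

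The other lists had fewer than 3 tested members. In the blood and marrow list, beside miR-451, miR-223 was at least 1.61-fold higher without passing (adjusted p = 0.0591) and was well above background on both hypertrophic, 1 prehypertrophic and 0 proliferative arrays, whereas miR-142-3p, miR-142-5p, miR-144, miR-150 and miR-155 were so on no array. miR-486, also found in red cells, was well above background on 1 proliferative and 1 hypertrophic array, and miR-150* on 1 hypertrophic array. In the endothelium list miR-126-5p was well above background on no array. Of the skeletal muscle list miR-208b was tested (-0.54, adjusted p = 0.225), and miR-1, miR-133a, miR-133b and miR-206 were well above background on no array. The epithelial miR-429 (-0.66, adjusted p = 0.244) and miR-205 (0.18, adjusted p = 0.797), as well as miR-29a (0.51), miR-30b (0.21), miR-30c (-0.14) and miR-221 (-0.86, adjusted p = 0.0534), did not pass. No member of the miR-34 and miR-449, bone and osteoblast, smooth muscle and pericyte, nerve or liver lists entered the test, and no viral name is on the array.

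At the first step, from the proliferative to the prehypertrophic zone, 5 of 226 miRNAs passed, all higher in the prehypertrophic zone. miR-322 was 4.27-fold higher (SE of log2 0.28, adjusted p = 0.00108), miR-503 4-fold (SE of log2 0.26, adjusted p = 0.00108), miR-322* 3.24-fold (SE of log2 0.30, adjusted p = 0.00906) and miR-22 2.48-fold (SE of log2 0.26, adjusted p = 0.0162). miR-181a-1* was at least 5.69-fold higher (adjusted p = 1.41e-04). With 3 of 7 members up (6 adjusted over the list alone), the list of miR-322 and miR-503 had a camera adjusted p of 2.35e-10, and adjusted p = 0.533 with an estimated correlation. One of the 4 tested miR-181 miRNAs rose (3 adjusted over the list alone; camera adjusted p = 0.00109, and adjusted p = 0.533 with an estimated correlation). None of the 18 Dlk1-Dio3 miRNAs passed over all miRNAs, and 4 were lower adjusted over the list alone (camera adjusted p = 9.39e-04, direction down, and adjusted p = 0.533 with an estimated correlation). The Dlk1-Dio3 call was lost without a filter on dim miRNAs (adjusted p = 0.163) and the miR-181 call with 2 times the floor (0.0676). Beyond the 5, the smallest p-values belonged to miR-451 (1.06 log2 units, adjusted p = 0.0513), miR-127 (-1.12, adjusted p = 0.0709), miR-329 (-1.06, adjusted p = 0.0958), miR-181a (at least 1.73-fold higher, adjusted p = 0.0958) and miR-99a (0.93, adjusted p = 0.14). miR-322* was well above background on 1 of the 2 proliferative arrays and its other probes were not above background, so the size of its rise is loose. Over the other settings the call of miR-322* held in 8 of 21, with log2 fold changes of 0.45 to 2.13, and that of miR-22 in 10 of 22. The count was 3 without the second prehypertrophic array, 10 without the second proliferative array (3 higher and 7 lower) and 0 without either hypertrophic array, although these arrays enter this contrast only through the shared spread.

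At the second step, from the prehypertrophic to the hypertrophic zone, 3 of 226 miRNAs passed, all higher in the hypertrophic zone. The arrays of these zones also lay in different rows of the slide. miR-451 was 8.68-fold higher (SE of log2 0.25, adjusted p = 1.99e-05), miR-2132 3.63-fold (SE of log2 0.27, adjusted p = 0.0032) and miR-126-3p at least 3.15-fold (adjusted p = 0.00413). Not past the threshold were miR-2137 (1.21 log2 units, adjusted p = 0.0587), miR-181a (1.17, adjusted p = 0.062), miR-21 (1.36), miR-2138 (1.05) and miR-1966 (1.07, adjusted p = 0.0737 for each of the 3), miR-181b (1.04, adjusted p = 0.129) and miR-322* (-1.03, adjusted p = 0.135). Camera placed 4 lists lower in the hypertrophic zone although no member passed on its own: let-7 and miR-98 (adjusted p = 0.00543), miR-199 and miR-214 (adjusted p = 0.0135), miR-322 and miR-503 (adjusted p = 0.0232) and cartilage (adjusted p = 0.0474), each with adjusted p = 0.675 with an estimated correlation. Adjusted over the list alone, 0, 3, 2 and 0 of their members were lower. In the list of miR-322 and miR-503, 6 of 7 tested members had negative log2 fold changes. The exception was miR-322 itself, at 0.21 (limma adjusted p = 0.64). Without the first hypertrophic array the calls of miR-199 and miR-214 (adjusted p = 0.0612), miR-322 and miR-503 (0.115) and cartilage (0.0961) were lost. The cartilage call was also lost without the first proliferative (0.0525), the first prehypertrophic (0.0541) or the second prehypertrophic array (0.127), and with the 75th percentile of all probes (0.0552), miRNAs above background on all 6 arrays (0.138), 2 times the floor (0.119) or the 2 zones alone (0.0568). That of miR-322 and miR-503 was also lost with normexp (0.0634) and with miRNAs above background on all 6 arrays (0.208), and that of miR-199 and miR-214 with quantile normalization (0.0581). With the title number run as a block the count of miRNAs was 5, and without either hypertrophic array it was 1.

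Of the 33 miRNAs that differed between the outer zones, 27 had a prehypertrophic mean between those of the other zones, 20 of the 20 falls and 7 of the 13 rises. Among all 226 tested miRNAs this was so for 82, but a large difference between the outer zones by itself makes a mean between them more likely. Curvature passed the limma threshold for 4 miRNAs. The prehypertrophic level lay above the middle of the outer zones for miR-181a-1* (adjusted p = 0.00475, with no size given because it was well above background on no proliferative array), miR-322* (curvature -1.36, SE 0.26, adjusted p = 0.0281) and miR-503 (-1.15, SE 0.23, adjusted p = 0.0281). It lay below the middle for miR-451 (1.03, SE 0.22, adjusted p = 0.0347), at 4.79 between 3.72 and 7.91, and in the deposited value table this value was -0.13. These curvature calls held in 10 of 20, 5 of 20, 7 of 21 and 4 of 20 other settings, in the order named. Without the first prehypertrophic array 2 miRNAs passed, and without any other single array 0. The F test over the 3 zones passed for 18 of 226 miRNAs, for 1 without either hypertrophic array and for 33 without the second proliferative array.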

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

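The alternatives here were planned. Leaving out one array in turn gave 1 to 45 miRNAs between the hypertrophic and proliferative zones (33 with all arrays; 1 without the second hypertrophic, 2 without the first hypertrophic 13 without the first and 45 without the second proliferative array), 0 to 10 between the prehypertrophic and proliferative zones (5 with all; 0 without either hypertrophic, 10 without the second proliferative and 3 without the second prehypertrophic array), 1 to 3 between the hypertrophic and prehypertrophic zones (3 with all; 1 without either hypertrophic array), 0 to 2 for curvature (4 with all; 2 without the first prehypertrophic array, otherwise 0), 1 to 33 for the F test (18 with all; 1 without either hypertrophic and 33 without the second proliferative array) and 8 to 14 list calls (12 with all). A lone array was then assumed to vary like the other zones. Counts that moved beyond 1.5 times under other settings were as follows. For hypertrophic minus proliferative they were 11 (75th percentile of all probes), 19 (quantile normalization), 15 (no scaling), 12 (median scaling), 20 (mean of all probes), 1 (no filter), 8 (2 times the floor) and 20 (deposited table). For prehypertrophic minus proliferative they were 3 (75th percentile of all probes), 1 (no scaling), 11 (total gene signal), 0 (no filter), 3 (above background on all 6 arrays), 9 (lower floor), 0 (2 times the floor), 10 (deposited table) and 0 (a fit of the 2 zones alone, which gives no curvature or F test). For hypertrophic minus prehypertrophic they were 5 (normexp), 8 (total gene signal), 1 (mean of all probes), 5 (no scaling), 1 (no filter), 6 (lower floor), 1 (2 times the floor) and 7 (eBayes with trend). For curvature they were 0 (75th percentile of all probes), 1 (quantile normalization), 0 (no scaling), 1 (median scaling), 0 (no filter), 1 (above background on all 6 arrays), 1 (2 times the floor) and 7 (deposited table). For the difference among the 3 zones, the F test, they were 31 (normexp), 11 (mean of all probes), 5 (75th percentile of all probes), 8 (no scaling), 11 (median scaling), 1 (no filter), 32 (lower floor) and 1 (2 times the floor). The miRNA lists gave 7 calls with all 6 arrays above background. List calls fell to 0 with an estimated correlation and to 0 with fry. Except where stated, the cause was not tested.

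With the title number run as a block, 46 miRNAs passed for hypertrophic minus proliferative, 6 for prehypertrophic minus proliferative, 5 for hypertrophic minus prehypertrophic (from 3), 3 for curvature and 19 for the difference among the 3 zones, and 12 list calls were made. With the slide row as a block, hypertrophic minus prehypertrophic gave 1, curvature 0 and the difference among the 3 zones 32. The row effect in that fit came from the proliferative pair alone, the only zone with arrays in both rows. Among miRNA values past the threshold, 378 of 573 under the alternatives stayed past it in the same direction, 194 lost it and 1 reversed, the curvature of miR-451 in the deposited table (-0.13). The fall of miR-675-3p became 0 with 2 times the floor, where both zones lie at the floor. Leaving out one array kept 113 such values and lost 109. Among values of named miRNAs not past the threshold, 68 of 675 passed it under the alternatives other than leaving out an array, and 18 changed sign without passing. The rise of miR-451 from the proliferative to the hypertrophic zone passed in 21 of 21 settings, at 1.90 to 6.09 log2 units. Other probes of called miRNAs that were above background had the sign of the brightest probe in 35 of 35 comparisons, 33 of them with at least 0.5 times its size; the exceptions were miR-181a (0.74 against 2.18, both limited by the floor) and 1 probe of miR-196a (-0.44 against -1.01). The remaining other probes, not above background, give no usable difference. Signal over background limits the dim end: 226 of 690 miRNAs could be tested, and those at the floor have only bounds.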

Other observations

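The limma comparison of the hypertrophic and proliferative zones was planned; the tests of neighbouring genes, of random lists, of the title number runs and of the 3 patterns were chosen after the values were seen. The falls toward the hypertrophic zone included miRNAs outside the Dlk1-Dio3 and let-7 lists that passed the limma threshold: miR-103 (log2 fold change -1.02, adjusted p = 0.0393), miR-130a (-1.06, adjusted p = 0.0425), miR-196a (-1.01, adjusted p = 0.0316) and, from one gene cluster, miR-99b (-1.03, adjusted p = 0.0298) and miR-125a-5p (-1.18, adjusted p = 0.0118), which lies beside let-7e (-1.39). The other arm of the miR-125a hairpin, miR-125a-3p, differed by 0.10 log2 units (adjusted p = 0.88). Averaged over the tested arms, the log2 fold change was -0.47 for the miR-99b hairpin and -0.54 for the miR-125a hairpin. miR-103 has a near-identical relative, so its probe can read both.

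A hypothesis was that miRNA genes lying next to each other differed together between the hypertrophic and proliferative zones, as members of one transcript might. Log2 fold changes of the tested arms of one hairpin were averaged before this test. Over 34 pairs of neighbouring hairpins within 10000 bases, the mean squared difference of log2 fold changes was 0.498 against a median of 1.02 in 10000 permutations (one-sided permutation p = 0.0011). Without the Dlk1-Dio3 list and the list of miR-322 and miR-503 it was 0.208 against 0.421 over 16 pairs (one-sided permutation p = 0.0134). Related neighbouring sequences that share probe signal could add to this. A second hypothesis was that the 27 tested names without a mouse miRNA gene in RefSeq, such as miR-2132 and miR-2138, stand above other miRNAs in the hypertrophic zone. Their median hypertrophic minus prehypertrophic log2 fold change was 0.27, and a share of 0.0028 of 10000 random lists matched on mean signal reached it; against the proliferative zone it was 0.18, with a share of 0.0028. miR-2132 and miR-2138, already seen to be higher in the hypertrophic zone, stayed among the 27, and no share was taken without them. What these probes measure was not tested.

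The first pattern weighed was the rise of miR-451 and miR-126-3p in the hypertrophic samples. With arrays not well above background set to the highest of the floor, the lowest signal well above background and their own, scaling as the cause is argued against: the smaller log2 difference, that of miR-126-3p, was at least 1.46 over 4 scalings (2 SE 0.60), which shifted the median miRNA by at most 0.48. Another probe of miR-126-3p, limited by the floor, differed by 1.04 under the scaling used here. A run difference common to all zones cannot produce the rise, because each run holds 1 array per zone. The smallest difference within a run, again of miR-126-3p, was at least 1.02, against 0.81 for 2 SDs of a difference. That limit used limma's prior SD (0.29 log2 units), shared across miRNAs, and not the spread of miR-126-3p itself. Blood and vessel cells at the border of the hypertrophic zone may be the source, and this stays open: of 9 other miRNAs in the blood and endothelium lists, 1 (miR-223) was well above background on both hypertrophic arrays and no proliferative array, while the others lay near the floor, where their absence excludes nothing. A change within the chondrocytes was not tested.

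The second pattern was the lower level of Dlk1-Dio3 miRNAs in the hypertrophic samples. A shift of all miRNAs by scaling would move random lists alike, but the median of the 18 members (-0.58) was reached by a share of 2e-04 of 10000 lists matched on mean signal. This share sets the list against other miRNAs under one scaling, so it does not settle the size of the fall itself. That median was -0.53 with the 75th percentile of all probes, -0.56 with quantile normalization, -0.49 with median scaling and -0.18 without scaling. The first proliferative array as the whole source of the list's lower median is argued against, since without it the median was -0.67. A share of at most 1e-04 reached it, the smallest that 10000 lists can give. That value sets the second proliferative array, of title number 16, against hypertrophic arrays of both runs. Within the run of title numbers 16 to 18 alone the median was -0.55, with 12 of 18 members lower. These shares treat miRNAs as independent, which members of one cluster need not be, and fry gave an adjusted p of 0.0934 for this list. The first proliferative array was not the higher of the proliferative pair for 6 of the 18. The size of the falls did depend on it: the 8 members that passed were all higher on it, without it their median went from -1.37 to -0.81 and 2 of the 8 passed, and over all miRNAs the falls past the threshold went from 20 to 3. Skeletal muscle in the proliferative samples stays open: miR-1, miR-133a, miR-133b and miR-206 gave 0 of 8 calls well above background there, but values at the floor exclude nothing, and miR-208b of the same list had a log2 fold change of -0.54; other tissues at the edge of that zone were not tested, and a difference of the zones themselves is a hypothesis found and tested on the same data.

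The third pattern did not follow the zones: miR-671-3p and miR-342-3p were higher in the arrays with title numbers 16 to 18 than 13 to 15, by 4.38 and 2.14 log2 units (adjusted p = 9.09e-04 for each), in every zone (5.07, 4.37 and 3.71, and 2.01, 2.11 and 2.30, in zone order). Scaling left the smaller at 1.93 or more, with a median shift of at most 0.21, and a defect of one probe is argued against for miR-342-3p, whose other probe differed by 2.67. This test was first run over both miRNAs together, which left it undecided, and then for each with the same limit of 1 log2 unit; for miR-671-3p it stayed undecided because its 3 other probes differed by 0.78, 1.54 and 2.90. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; the real split called 2 miRNAs and the highest other 1. Differences between the mice or the preparations of the runs are candidate sources that the labels do not resolve.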
